A study of Mus musculus with 12 samples.

How the data were processed

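RNA was measured in the hippocampus of 12 C57BL/6 wild-type mice, 3 in each group of treatment (stigmasterol or vehicle, by intraperitoneal injection) and time (1 h or 6 h). Per the labels, total RNA was extracted with RNAqueous-Micro kits, samples with a RIN of at least 7 were used, and libraries were made with the TruSeq mRNA kit. The labels disagree on the compound, since the treatment field names beta-sitosterol at 100 mg/kg and the other fields name stigmasterol. The labels do not give the sex, the age, the clock time of injection, the composition of the vehicle or the strandedness of the libraries. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt, STAR 2.4.2a, HTSeq 0.6.1p1, DESeq2 1.10.1 and DESeq were used with genome build GRCm38, with no statement of their order.

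The deposited raw table holds counts, that is whole numbers of reads per gene, made by the authors. The deposited normalized table holds signal made by the authors, in which each library's counts were divided by 1 size factor, and the largest difference from that rule was 0.0161. The counts were the input of every test, and the normalized values served in 1 alternative. Group and replicate number were read from the sample titles. Genes were matched by identifier to GENCODE M21, which gave coordinates for 21501 of 21532 genes and none for 31, and 14 symbols were shared by more than 1 identifier. Every gene in the table had a count of at least 6 in some library, so genes with fewer counts are absent from the table.

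Tests were run in R 4.3.3. With edgeR 4.0.16, genes were kept by filterByExpr (18382 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries. The common biological coefficient of variation was 0.123. The 6 contrasts tested were stigmasterol against vehicle at 1 h, at 6 h and averaged, the difference of those effects, and 6 h against 1 h within vehicle and within stigmasterol mice. The p values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. SE stands for the standard error of the log2 fold change, derived as its absolute value over the square root of the quasi-likelihood F statistic. Expression values in CPM used TMM-scaled totals. Total counts lay between 27613253 and 42043875 per library. Over genes with a mean of at least 1 CPM, the median SE of a log2 fold change was 0.117 at 1 h and 0.117 at 6 h.

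Gene lists for pathways, cell types and tissue quality, 34 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, for lists of at least 5 tested genes. Camera with an estimated correlation and the rotation test fry were run beside it. Within a list, p was also adjusted over the list alone.

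The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 12 higher and 12 lower genes past the threshold with a mean of at least 1 CPM and groups that did not overlap, leaving out predicted or unnamed transcripts. Where fewer than 5 passed, it named the 10 genes with the smallest p. It also allowed up to 4 members with the smallest p of each called list, 1 or 2 such members of each other pathway list for the comparisons of stigmasterol with vehicle, and a fixed set of genes, of which Fos, Arc, Npas4, Egr1, Fkbp5, Sgk1, Abca1, Kpna1 and Sphk1 are given. Some genes that the rule names are not reported here, were left out of the repeats of named genes, and were not replaced by others.

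Alternatives fixed with the design were DESeq2 size factors, upper-quartile factors, no filter, a stricter filter (at least 1 CPM in all libraries of a group and a mean of 2 CPM), the DESeq2 1.42.0 Wald test, limma-voom, a robust quasi-likelihood model, limma-trend on log2 of the authors' normalized values plus 1, only the groups compared, choroid plexus marker content as a covariate, an adjusted p of 0.1, and leaving out each library in turn. Removal of each library's trend with GC content and length (splines with 5 degrees of freedom), alone and with the plexus covariate, and leaving out vehicle libraries 4 and 9 at 1 h together were added after the data had been seen. Splits of the libraries were refitted, all 10 for each comparison of 3 with 3 and 50 for the others, the real split included in each number. No library was left out of the reported values. Other splits were required of every comparison, and the predictions tested with them and with the other explanations were written after the results were seen. Bcl3, Per3 and the clock genes fell outside the naming rule and were chosen after their values were seen. Reads were not used here.

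The procedure was tested on simulated data with 18199 tested genes and changes placed in the 1 h comparison. It recovered 3 of 50 genes changed 1.25-fold, 27 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 49 of 50 changed 4-fold, with 4 false calls, and gave 0 calls at 6 h where nothing had been changed. Genes were simulated as independent, so the simulation does not test the lists under correlated genes. Apart from the placed changes each gene had the same mean in all libraries, with no GC or tissue structure. The recovered shares therefore do not describe single genes under such structure.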

Results

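Hippocampal RNA from 12 C57BL/6 mice was compared between animals injected with stigmasterol and animals injected with vehicle, with tissue taken 1 h or 6 h after the injection. Each of the 4 groups held 3 mice and each mouse gave 1 library. One field of the sample labels names the injected compound as beta-sitosterol at 100 mg/kg, whereas the agent, the sample descriptions and the series title name stigmasterol; the word stigmasterol is used below for that group. The table of raw counts held 21532 genes, of which 16108 were protein coding. Total counts were 42043875, 38117958 and 40529407 in the stigmasterol libraries at 1 h (replicates 1, 11 and 8), 32345543, 28676812 and 33217636 in the vehicle libraries at 1 h (replicates 4, 5 and 9), 32389002, 30574980 and 32668059 in the stigmasterol libraries at 6 h (replicates 13, 22 and 23), and 33146956, 34805747 and 27613253 in the vehicle libraries at 6 h (replicates 12, 14 and 21). After low counts were removed, 18382 genes were tested. The Y-linked gene Ddx3y lay between 29.9 and 47.3 CPM and Xist at no more than 0.486 CPM in all 12 libraries, the pattern of male tissue.

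RNA of marker genes of neighbouring structures differed between libraries, as the plot of tissue and cell marker lists shows. Choroid plexus markers averaged 0.80 and 1.11 log2 CPM in vehicle replicates 4 and 9 at 1 h and between 2.85 and 5.84 in the other 10 libraries. Ttr, the main secreted product of the choroid plexus epithelium, stood at 31.0 and 40.3 CPM in those 2 libraries and between 356 and 4438 CPM elsewhere. Striatum markers averaged 4.67 log2 CPM in stigmasterol replicate 8 at 1 h and at most 3.33 in any other library. The first 3 principal components held 26.9%, 17.8% and 11.9% of the variance, and the first separated vehicle replicates 4 and 9 at 1 h at its low end from stigmasterol replicate 22 at 6 h at its high end.

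**Figure D1:**
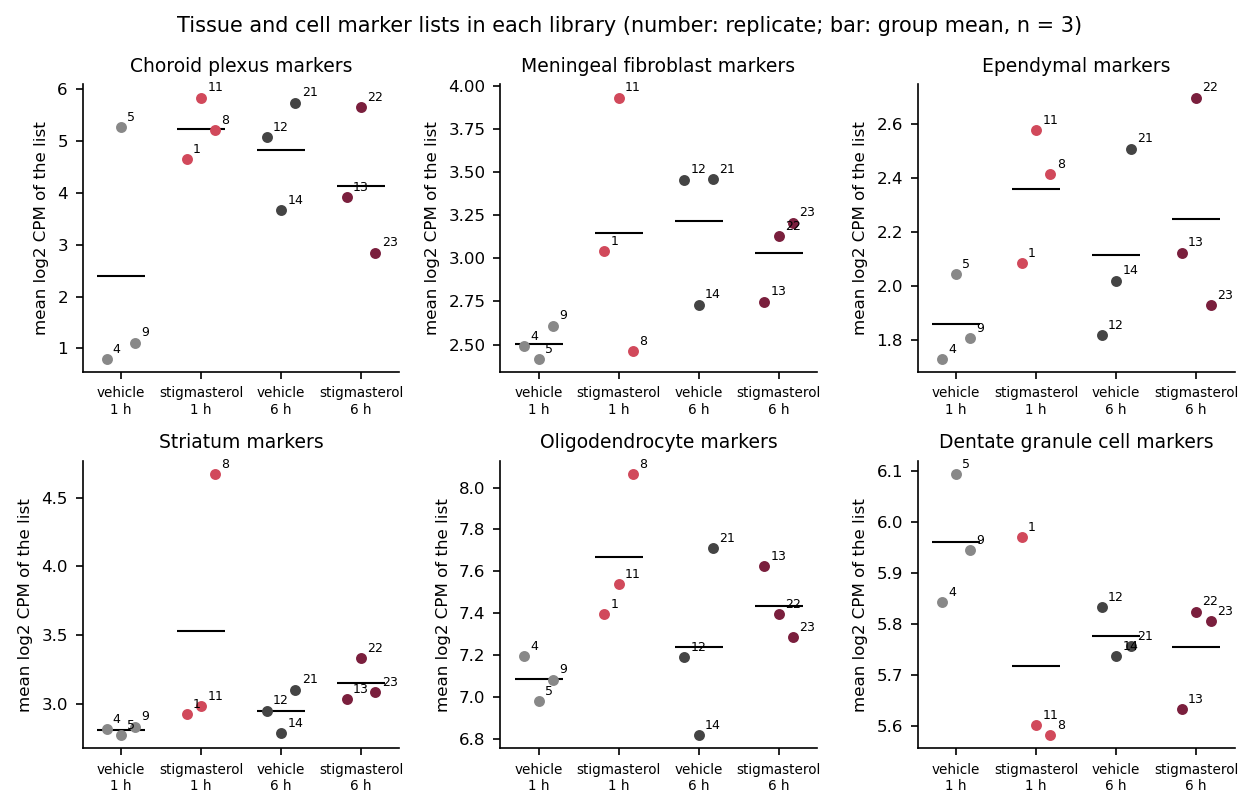
Mean log2 CPM of 6 lists of tissue and cell markers in each library. Points are single mice, numbers give the replicate, and bars give the mean of 3 mice.

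One hour after the injection, the lists of immediate early and activity-regulated genes and of oligodendrocyte markers were called higher in stigmasterol mice, and dentate granule cell markers lower. These were shifts of whole gene lists, and they passed the list test only when a preset correlation between genes was used (adjusted p = 0.487 with an estimated one). Markers of tissues that line the brain were called higher on the same terms, but the choroid plexus list not without vehicle replicates 4 and 9 (median 0.0152), the ependymal list not with plexus content as a covariate, and the meningeal median fell from 0.78 to 0.23 without stigmasterol replicate 11. No single gene changed at an adjusted p below 0.05. The genes with the smallest p were led by the AP-1 subunit Jund and the translationally controlled tumour protein Tpt1.

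With edgeR, 0 genes passed an adjusted p of 0.05 at 1 h, while 1383 had an unadjusted p below 0.05, 914 of them higher and 469 lower with stigmasterol. The smallest adjusted p was 0.441. limma-voom and limma-trend also gave 0 genes, and DESeq2 gave 21, of which 20 were higher and 1 lower. The 2 groups did not overlap for 2902 genes (15.8% of those tested, where 10% would be met by chance).

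The 10 genes with the smallest p at 1 h were all higher with stigmasterol, did not overlap between the groups, and shared an adjusted p = 0.441. Fold changes at 1 h also rose with GC content across all genes (Spearman correlation 0.404). The GC slope of a library used log2 CPM relative to each gene's mean over all libraries, for genes averaging above 1 log2 CPM. Per 10 points of GC content, it lay between -0.145 and -0.0875 in the vehicle libraries and between -0.0813 and 0.178 in the stigmasterol libraries. Jund (chr8, 70698949 to 70700616) encodes an AP-1 transcription factor and had a log2 fold change of 0.87 ± 0.15 (SE), from 12 ± 2.14 to 22 ± 2.68 CPM (SD, n = 3). Tpt1 (chr14, 75845093 to 75848525), a regulator of growth and survival, had a log2 fold change of 0.67 ± 0.12, and Endog, a mitochondrial nuclease, one of 0.88 ± 0.17. Metrn, a secreted factor of glial cells, was higher by 0.87 ± 0.17 on the log2 scale and Olig1, a transcription factor of the oligodendrocyte lineage, by 0.66 ± 0.14, from 89.8 ± 9.93 to 142 ± 29.9 CPM (SD, n = 3). Ccdc85b, which binds the activating transcription factor ATF4, was at 18.2 ± 4.46 CPM against 7.68 ± 2.24 CPM (SD, n = 3), a log2 fold change of 1.25 ± 0.25. Scand1, a protein with a SCAN domain, showed the widest ratio of the 10 at a log2 fold change of 2.33 ± 0.48, though from 0.335 ± 0.129 CPM (SD, n = 3). The ribosomal stalk protein gene Rplp2 (0.49 ± 0.10), Grcc10 (0.71 ± 0.14) and the DNA-repair associated Rex1bd (0.59 ± 0.13) completed the group, each given as log2 fold change ± SE.

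**Figure D2:**
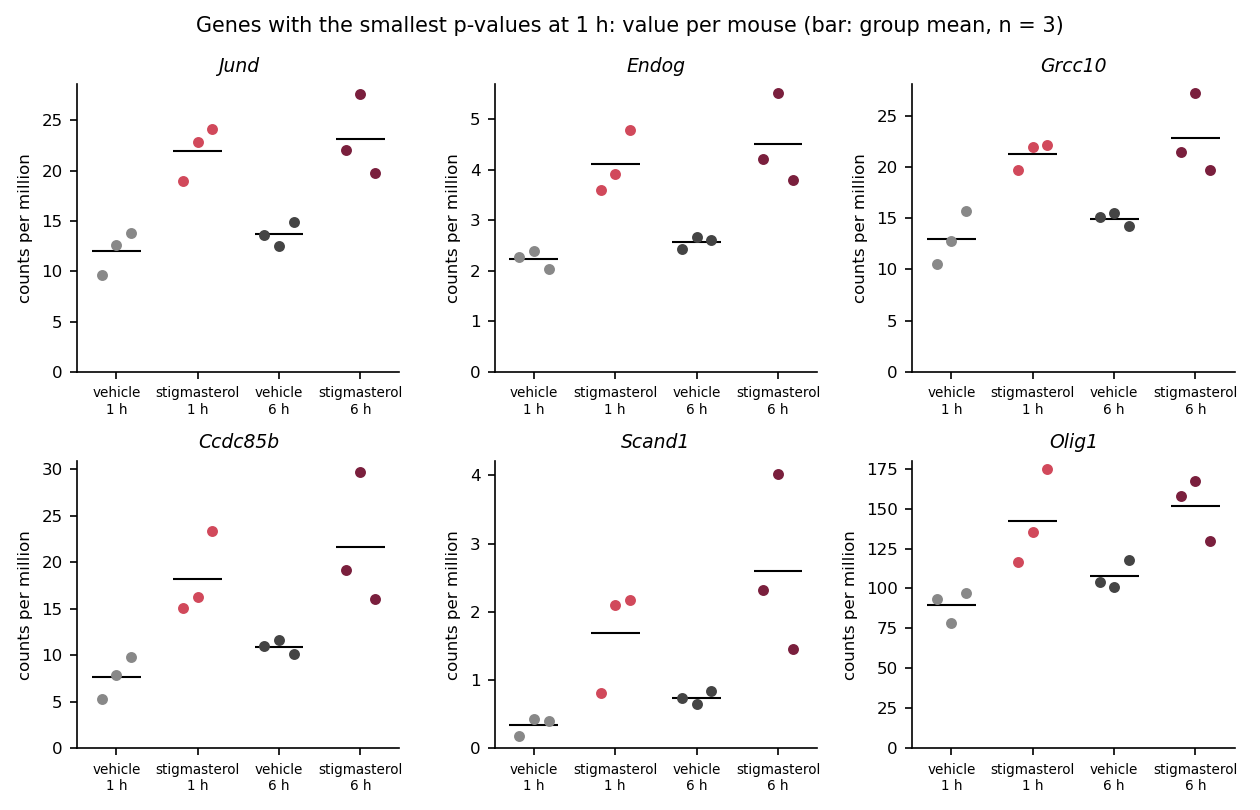
CPM of Jund, Endog, Grcc10, Ccdc85b, Scand1 and Olig1 in each mouse at 1 h and 6 h. Bars give the mean of 3 mice. None of these genes passed an adjusted p of 0.05 at either time.

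Immediate early genes mark neurons that have recently fired. Of the 39 such genes tested, 34 were higher with stigmasterol at 1 h, with a median log2 fold change of 0.27 (camera adjusted p = 1.51e-05, and adjusted p = 0.487 with an estimated correlation). None passed over all genes, 10 had an unadjusted p below 0.05, and 1 passed when adjusted over the list alone. Egr4 was at 13.3 ± 4.36 CPM against 6.35 ± 0.279 CPM (SD, n = 3), a log2 fold change of 1.06 ± 0.24 (adjusted p = 0.534), and Junb had 0.68 ± 0.19 (adjusted p = 0.649). Among the activity genes named in advance, Egr1 had a log2 fold change of 0.64 ± 0.23, Arc, a synaptic protein needed for lasting plasticity, 0.70 ± 0.38, Fos 0.52 ± 0.37 and Npas4 0.35 ± 0.29, with adjusted p = 0.649, 0.692, 0.730 and 0.768 in that order. The list kept its direction and its place under the threshold in all 12 alternatives that used the same list test, with a median between 0.10 and 0.38. Library means of the list overlapped between the groups, with stigmasterol replicate 11 at 3.82 log2 CPM and the vehicle libraries between 3.79 and 3.87. The highest mean, 4.32, was that of stigmasterol replicate 8, which was also highest in striatum markers, and the list median was 0.10 without it.

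All 15 oligodendrocyte markers were higher at 1 h (median log2 fold change 0.48, camera adjusted p = 9.39e-07, and adjusted p = 0.487 with an estimated correlation), 7 of them at an unadjusted p below 0.05. Over the alternatives with the same list test the median lay between 0.25, without stigmasterol replicate 8, and 0.77, without vehicle replicates 4 and 9 together. Replicate 8 was also highest in striatum markers. Its oligodendrocyte mean was the highest, 8.06 log2 CPM against at most 7.54 in the other stigmasterol libraries at 1 h. The tight junction gene Cldn11 of myelin had a log2 fold change of 0.68 ± 0.21 (adjusted p = 0.649). Dentate granule cell markers went the other way: 9 of 11 were lower, with a median of -0.32 (camera adjusted p = 0.000566, and adjusted p = 0.487 with an estimated correlation), between -0.47 without stigmasterol replicate 1 and -0.20 without stigmasterol replicate 8. Prox1, which maintains granule cell identity, was at 133 ± 22.9 CPM against 168 ± 16.7 CPM (SD, n = 3), a log2 fold change of -0.34 ± 0.11, and the channel gene Trpc6 had -0.35 ± 0.12 (adjusted p = 0.649 for each). GABA signalling genes had a median of -0.09 (camera adjusted p = 0.0251, and adjusted p = 0.487 with an estimated correlation). The vesicular transporter gene Slc32a1, at 0.26 ± 0.13, went against the direction of the list. The GABA signalling list did not pass without stigmasterol replicate 8 (adjusted p = 0.104), vehicle replicate 5 (0.0578) or vehicle replicate 9 (0.0709), and it passed in 2 of the 6 alternatives with the same list test that did not leave out a single library.

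Markers of tissues that border the hippocampus were also higher at 1 h. The median log2 fold change was 1.51 for 15 choroid plexus markers (camera adjusted p = 2.60e-10), 0.40 for 11 ependymal markers (2.90e-05), 0.78 for 13 meningeal fibroblast markers (1.51e-05) and 1.06 for 13 striatum markers (0.000359). The meningeal median was 0.23 without stigmasterol replicate 11 (adjusted p = 0.0418). The choroid plexus median was 4.54 without vehicle replicate 5, 0.0152 without vehicle replicates 4 and 9 together and -0.0233 with plexus content as a covariate. The ependymal list did not pass in 2 of the 6 alternatives with the same list test other than leaving out a single library, both with plexus content as a covariate, where its median was as low as 0.0648 and its adjusted p as high as 0.406. Every member of these 4 lists was higher, and each list had an adjusted p = 0.487 with an estimated correlation. The collagen genes Col3a1 (0.79 ± 0.22) and Col1a1 (0.74 ± 0.21) were among 6 meningeal genes that passed when adjusted over the list alone, against 0 over all genes. In the choroid plexus list the anion transporter gene Slc13a4 had a log2 fold change of 1.36 ± 0.54 and the secreted BMP antagonist gene Sostdc1 one of 1.56 ± 0.76. The cilia genes Dynlrb2 (0.92 ± 0.30) and Cfap126 (0.88 ± 0.32) led the ependymal list. Among striatum markers, Ppp1r1b, the dopamine-regulated phosphatase inhibitor, had a log2 fold change of 1.06 ± 0.35. Without stigmasterol replicate 8 the striatum median was 0.05 and the list no longer passed (adjusted p = 0.475).

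Smaller shifts in stress and defence genes accompanied these. Endoplasmic reticulum stress genes (19 of 20 higher, median 0.15, camera adjusted p = 0.000447), interferon-stimulated genes (23 of 26, 0.18, 0.00315), inflammatory genes (17 of 23, 0.18, 0.0178) and heat shock genes (11 of 17, 0.03, 0.0325) were called higher. With an estimated correlation their adjusted p lay between 0.487 and 0.554. Sdf2l1, a chaperone partner of the secretory pathway, had a log2 fold change of 0.61 ± 0.19 and Pdia4 0.33 ± 0.13. Ifitm1 (0.86 ± 0.24), Nfkbia (0.39 ± 0.16), Bst2 (0.57 ± 0.23), Rtp4 (0.50 ± 0.22), Hspa1b (0.70 ± 0.22) and Dnajb1 (0.24 ± 0.08) were the other leading members. Cytosolic ribosomal protein genes were higher in 33 of 40 cases (median 0.09, camera adjusted p = 0.000287, and adjusted p = 0.536 with an estimated correlation), 3 of them when adjusted over the list alone, among them Rps16 (0.54 ± 0.12). Interferon-stimulated genes did not pass without stigmasterol replicate 11 (adjusted p = 0.366), endoplasmic reticulum stress genes without stigmasterol replicate 8 (0.116), and inflammatory and ribosomal protein genes without vehicle replicate 5 (0.0578 and 0.0611). Heat shock genes did not pass without stigmasterol replicate 8 (0.0635) or 11 (0.0731) or vehicle replicate 4 (0.17, with a median of -0.00473) or 9 (0.0532). Without stigmasterol replicate 8 or 11 or vehicle replicate 9 their median did not fall, at 0.0497, 0.0449 and 0.0453 in that order. In the 6 alternatives with the same list test that kept all or all but 2 libraries, heat shock and endoplasmic reticulum stress lists passed in 3 each, interferon genes in 4, and inflammatory and ribosomal protein genes in 5 each. Mitochondrially encoded genes were not called.

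Genes that plant sterols or stress hormones regulate moved little at 1 h. Cholesterol synthesis and uptake genes had a median log2 fold change of 0.08 (21 of 25 higher, camera adjusted p = 0.0139), liver X receptor targets 0.08 (14 of 16, 0.0391) and glucocorticoid-responsive genes 0.12 (24 of 28, 0.0303). With an estimated correlation their adjusted p lay between 0.487 and 0.646. The cholesterol exporter gene Abca1 had a log2 fold change of 0.01 ± 0.08. The liver X receptor targets Pltp (0.42 ± 0.18) and Smpdl3a (0.24 ± 0.11) were the leading members of that list. The glucocorticoid targets Fkbp5 (0.00 ± 0.23), Sgk1 (0.41 ± 0.20) and Arrdc2 (0.51 ± 0.23) had adjusted p = 0.999, 0.678 and 0.662. Cholesterol genes did not pass without stigmasterol replicate 1 (adjusted p = 0.0515) or 8 (0.323) or vehicle replicate 5 (0.0749) or 9 (0.303). Glucocorticoid-responsive genes did not pass without stigmasterol replicate 8 (0.528) or vehicle replicate 5 (0.0784). Liver X receptor targets did not pass without stigmasterol replicate 8 (0.190) or 11 (0.0524) or vehicle replicate 4 (0.0846) or 5 (0.0800). Without stigmasterol replicate 8 the cholesterol, glucocorticoid and liver X receptor medians were 0.0520, 0.0317 and 0.0247. The cholesterol median was 0.0266 without vehicle replicate 9, and the liver X receptor median 0.16 without stigmasterol replicate 11. In the 6 alternatives with the same list test that kept all or all but 2 libraries, cholesterol genes passed in 6, glucocorticoid-responsive genes in 4 and liver X receptor targets in 2. Importin and sphingosine pathway genes were not called. Kpna1, the nuclear import receptor, had -0.12 ± 0.10 and Sphk1, which makes sphingosine 1-phosphate, 0.77 ± 0.35. The lists of circadian, glutamate receptor, and serotonin and neuropeptide genes were not called either, with Cry1 at 0.26 ± 0.11, Gria1 at -0.24 ± 0.09 and Penk at 1.20 ± 0.46.

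At 6 h after the injection, the list of cholesterol synthesis and uptake genes was called higher in stigmasterol mice, though not when the correlation was estimated (adjusted p = 0.786). Ribosomal protein, glucocorticoid-responsive and interneuron genes were called higher as lists too, the last 2 not when stigmasterol replicate 23 or 13, respectively, was left out. No other list passed at 6 h when the correlation was estimated (adjusted p = 0.786 or more). Jund, Endog, Grcc10, Scand1 and Ccdc85b were again among the genes that stood out most. Fold changes rose with GC content here too (Spearman correlation 0.195 across all genes). A GC trend of the libraries stays open as an explanation for a part of these changes. Stigmasterol replicate 23 had the lowest GC slope of all libraries (-0.154). Its mean over the 10 genes with the smallest p at 1 h was 3.90 log2 CPM, against 3.48 to 3.53 in the vehicle libraries. In that library the GC slope alone would not give the higher level. No single gene changed at an adjusted p below 0.05, and the lists of border-tissue markers were not called.

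With edgeR, 0 genes passed at 6 h and 754 had an unadjusted p below 0.05, 301 higher and 453 lower. The smallest adjusted p was 0.950. limma-voom and limma-trend gave 0 genes and DESeq2 gave 4, of which 3 were higher and 1 lower. Groups did not overlap for 1511 genes (8.22%, where 10% would be met by chance). Jund was at 23.2 ± 4.06 CPM against 13.7 ± 1.20 CPM (SD, n = 3), a log2 fold change of 0.76 ± 0.15 (adjusted p = 0.950). Endog had 0.81 ± 0.17, Scand1 1.80 ± 0.42, Grcc10 0.61 ± 0.14 and Ccdc85b 0.98 ± 0.24 (adjusted p from 0.950 to 1.00). Spaca6 (chr17, 17827158 to 17843009), known for its part in sperm and egg fusion, was lower, at 50.4 ± 3.72 CPM against 70.9 ± 7.16 CPM (SD, n = 3) and a log2 fold change of -0.49 ± 0.10. The RNA-binding protein gene Hnrnpa0 (0.41 ± 0.08), Mrfap1 (0.31 ± 0.06), the growth cone protein gene Basp1 (0.39 ± 0.08) and the mitochondrial iron-sulfur protein gene Cisd1 (0.29 ± 0.07) were higher.

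All 25 cholesterol synthesis and uptake genes had a positive log2 fold change at 6 h, with a median of 0.15 (camera adjusted p = 4.54e-06, and adjusted p = 0.786 with an estimated correlation). No member had an unadjusted p below 0.05. The squalene epoxidase gene Sqle had a log2 fold change of 0.21 ± 0.10 and the mevalonate decarboxylase gene Mvd one of 0.31 ± 0.16, from 19.4 ± 1.89 to 23.9 ± 0.676 CPM (SD, n = 3). This list kept its place under the threshold in all 11 alternatives that used the same list test, with a median between 0.09 and 0.22. Its library means overlapped between the groups, with stigmasterol replicate 22 at 4.88 log2 CPM and vehicle replicate 21 at 4.91. Liver X receptor targets were not called, and Abca1 had -0.15 ± 0.08 (adjusted p = 1.00).

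Glucocorticoid-responsive genes had a median log2 fold change of 0.27 at 6 h (23 of 28 higher, camera adjusted p = 0.00115, and adjusted p = 0.786 with an estimated correlation). The metallothionein gene Mt2 had 0.36 ± 0.14 and the lipase gene Pnpla2 0.31 ± 0.13. Without stigmasterol replicate 23 the median was 0.02 and the list no longer passed (adjusted p = 0.609). Fkbp5 (0.34 ± 0.23) was at 157 CPM in that library and at most 113 CPM in any other, and had -0.08 without it. Sgk1 had 0.02 ± 0.20. GABAergic interneuron markers were higher in 14 of 15 cases (median 0.14, camera adjusted p = 0.00264, and adjusted p = 0.786 with an estimated correlation), led by Slc32a1 (0.36 ± 0.13) and the homeobox gene Dlx6 (0.42 ± 0.19). Without stigmasterol replicate 13 this list did not pass (adjusted p = 0.140).

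Cytosolic ribosomal protein genes (37 of 40 higher, median 0.09, camera adjusted p = 4.54e-06), oligodendrocyte markers (14 of 15, 0.25, 0.00384), immediate early genes (29 of 39, 0.11, 0.00221), endoplasmic reticulum stress genes (18 of 20, 0.09, 0.00733), heat shock genes (16 of 17, 0.08, 0.0192) and interferon-stimulated genes (21 of 26, 0.07, 0.0425) were also called higher at 6 h. Their adjusted p with an estimated correlation was 0.786 or 0.806. Without stigmasterol replicate 13, oligodendrocyte (adjusted p = 0.162), endoplasmic reticulum stress (0.121), heat shock (0.260) and interferon (0.162) lists did not pass. Their medians were then 0.14, 0.06, 0.04 and 0.02. Without vehicle replicate 14 the same 4 lists did not pass (0.464, 0.255, 0.255 and 0.270), with medians of 0.07, 0.05, 0.03 and -0.00824. Interferon genes also failed to pass without stigmasterol replicate 22 (0.158) or vehicle replicate 12 (0.927, with a median of -0.0386), heat shock genes without stigmasterol replicate 23 (0.0620), and immediate early genes without vehicle replicate 21 (0.0666). Ribosomal protein genes did not pass with plexus covariate and trend removal together (median 0.0305, adjusted p = 0.0836), and interferon genes passed in 4 of the 5 alternatives with the same list test that kept all libraries. Leading members were Rplp2 (0.28 ± 0.10), Rpl27 (0.43 ± 0.19), Cldn11 (0.36 ± 0.21), Mal (0.32 ± 0.21), Gadd45g (0.53 ± 0.16), Junb (0.52 ± 0.19), Chac1 (0.25 ± 0.13), Sdf2l1 (0.30 ± 0.20), Hspa1a (0.56 ± 0.22), Hspa1b (0.35 ± 0.22), Psmb8 (0.44 ± 0.18) and Irf7 (0.25 ± 0.18). Fos (0.06 ± 0.39), Arc (0.24 ± 0.38), Npas4 (-0.11 ± 0.29), Egr1 (0.07 ± 0.24), Kpna1 (0.02 ± 0.10) and Sphk1 (-0.19 ± 0.34) had an adjusted p = 1.00. Inflammatory genes were not called. Lcn2, a secreted acute-phase protein, was at 24.0 CPM in stigmasterol replicate 23 and at most 3.27 CPM in any other library, which gave a log2 fold change of 1.86 ± 0.79, and -0.59 without that library. Of the other uncalled lists, Nfil3 (0.30 ± 0.13), Grm5 (0.09 ± 0.09), Sst (0.27 ± 0.16) and S1pr5 (0.41 ± 0.18) were the leading members. All 15 choroid plexus markers were lower (median -0.39), and the list was not called.

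**Figure D3:**
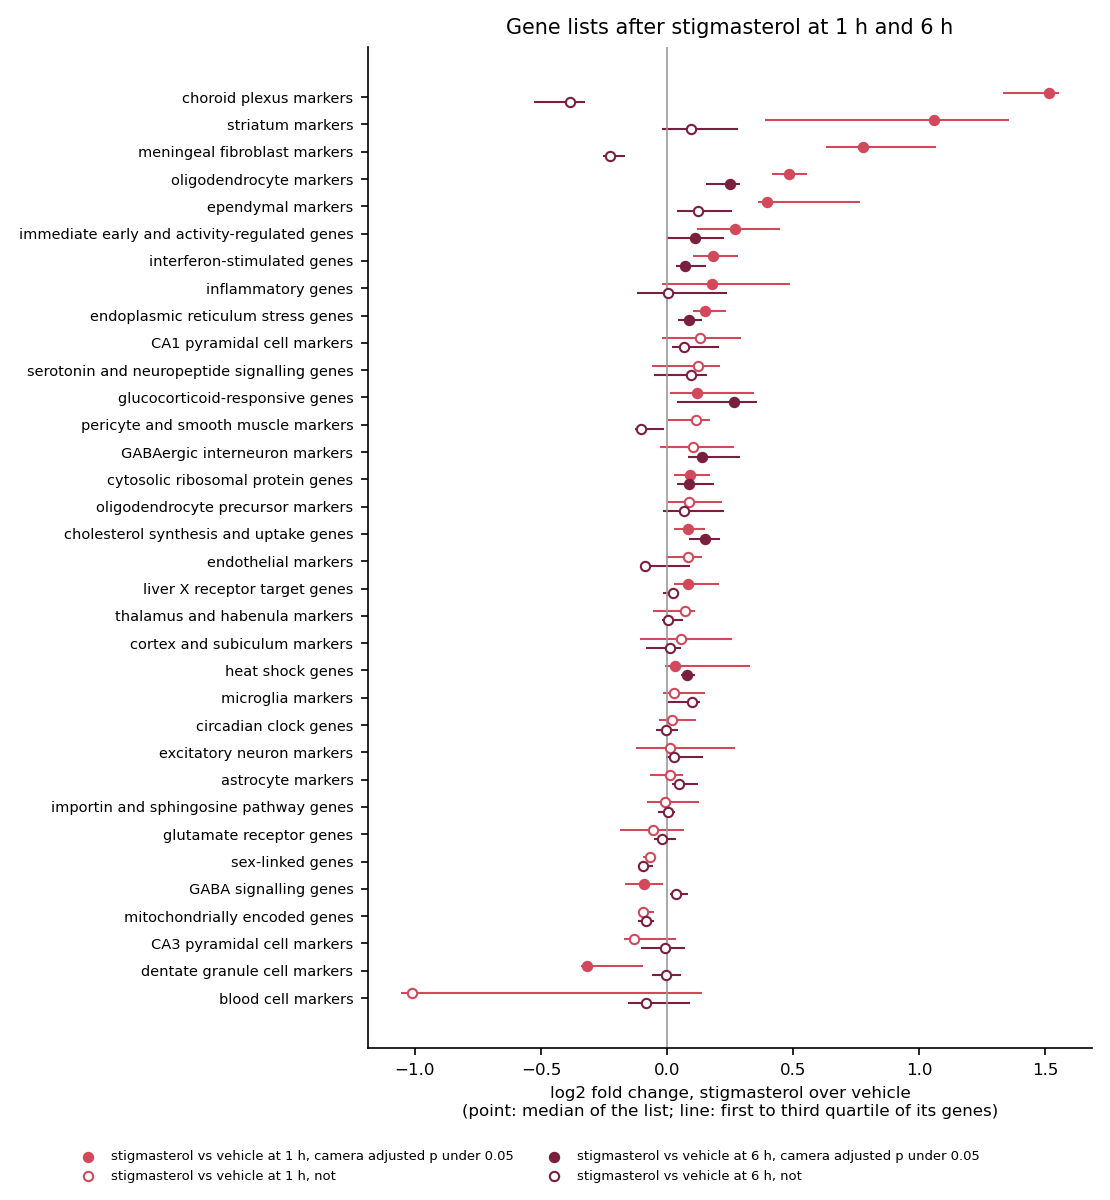
Median log2 fold change of stigmasterol over vehicle for each of 34 gene lists at 1 h and 6 h. Lines run from the first to the third quartile of the genes in a list. Filled points had a camera adjusted p below 0.05 with a preset correlation of 0.01, and none did with an estimated correlation.

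Averaged over both times, the genes closest to a change with stigmasterol were again Jund and Endog, followed by Grcc10, Scand1, Ccdc85b and Tpt1. The averaged fold changes also rose with GC content (Spearman correlation 0.376 across all genes), so a GC trend stays open here too as a part of the change. Immediate early, cholesterol, oligodendrocyte, ependymal and ribosomal protein lists were higher under every alternative that kept the list test, and none passed when the correlation was estimated (adjusted p = 0.550 or more).

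With edgeR, 0 genes passed an adjusted p of 0.05 for the averaged effect and 7 passed 0.1, all of them higher; 1685 had an unadjusted p below 0.05 (863 higher, 822 lower). limma-voom and limma-trend gave 0 genes and DESeq2 gave 103 (87 higher, 16 lower). edgeR gave 26 genes without stigmasterol replicate 23 at 6 h, 2 without stigmasterol replicate 1 at 1 h and 0 without any other single library. Jund (0.82 ± 0.11) and Endog (0.84 ± 0.12) had an adjusted p = 0.0648, Grcc10 (0.66 ± 0.10), Scand1 (2.07 ± 0.32) and Ccdc85b (1.11 ± 0.17) an adjusted p = 0.0678, and Tpt1 (0.53 ± 0.09) an adjusted p = 0.0802. Olig1 (0.58 ± 0.10), Uqcrq (0.44 ± 0.08), Hnrnpa0 (0.33 ± 0.06) and Rplp2 (0.38 ± 0.07) followed with an adjusted p from 0.130 to 0.139. The fold changes at 1 h and 6 h correlated weakly across all genes (Pearson r = 0.192, and -0.12 without stigmasterol replicate 22 at 6 h).

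Of 34 lists, 15 were called for the averaged effect, 14 higher and 1 lower, and none with an estimated correlation (smallest adjusted p = 0.550). Immediate early genes had a median log2 fold change of 0.16 (camera adjusted p = 2.41e-06), with Egr4 at 0.80 ± 0.17 and Junb at 0.60 ± 0.13, and 3 members passed when adjusted over the list alone against 0 over all genes. Cholesterol genes had a median of 0.11 with all 25 higher (1.06e-05), oligodendrocyte markers 0.34 (6.84e-07), ependymal markers 0.34 (0.000131) and ribosomal protein genes 0.09 (6.84e-07). Over the alternatives with the same list test the ependymal median lay between 0.14 and 0.43, and the ribosomal protein median between 0.03 and 0.16. Olig2 (0.34 ± 0.13), Ddit4 (0.36 ± 0.12) and Hspa5 (0.24 ± 0.10) were among the leading members of the oligodendrocyte precursor, glucocorticoid and endoplasmic reticulum stress lists. Dentate granule cell markers had a median of -0.13 (camera adjusted p = 0.0148), with Trpc6 at -0.31 ± 0.09 and Stxbp6 at -0.22 ± 0.09. It did not pass without replicate 5 of the 1 h vehicle mice (adjusted p = 0.0834), replicate 11 of the 1 h stigmasterol mice (0.0843), or replicates 13 or 23 of the 6 h stigmasterol mice (0.0680 and 0.0552).

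Of the remaining lists called for the averaged effect, the median log2 fold change and camera adjusted p were glucocorticoid-responsive genes (0.20, 0.000436), interferon-stimulated genes (0.15, 0.000932), heat shock genes (0.04, 0.00422), endoplasmic reticulum stress genes (0.12, 8.09e-05), GABAergic interneuron markers (0.10, 0.0233), oligodendrocyte precursor markers (0.07, 0.0475), choroid plexus markers (0.53, 0.000436), meningeal fibroblast markers (0.24, 0.0328) and striatum markers (0.51, 0.00393). Their adjusted p with an estimated correlation lay between 0.550 and 0.694. The choroid plexus median was -0.17 without vehicle replicates 4 and 9 at 1 h together, 0.00510 with plexus content as a covariate, and 2.11 without vehicle replicate 5 at 1 h. Without stigmasterol replicate 22 at 6 h the median of choroid plexus markers, stigmasterol vs vehicle averaged over both times, was -0.0336. Left-out libraries are given as treatment, time and replicate. Glucocorticoid-responsive genes did not pass without stigmasterol 6 h 23 (0.0855). Interferon-stimulated genes did not pass without stigmasterol 1 h 11 (0.0721). GABAergic interneuron markers did not pass without stigmasterol 1 h 11 (0.0914), stigmasterol 6 h 13 (0.153), vehicle 1 h 4 (0.0570). Oligodendrocyte precursor markers did not pass without stigmasterol 1 h 11 (0.0639) or 8 (0.0692), stigmasterol 6 h 13 (0.215) or 23 (0.0709), vehicle 1 h 5 (0.151), vehicle 6 h 12 (0.157). Meningeal fibroblast markers did not pass without stigmasterol 1 h 11 (0.639), stigmasterol 6 h 22 (0.0727) or 23 (0.166), vehicle 1 h 5 (0.0794), vehicle 6 h 14 (0.273). Striatum markers did not pass without stigmasterol 1 h 8 (0.217). Without vehicle replicates 4 and 9 at 1 h together, heat shock (adjusted p = 0.106) and endoplasmic reticulum stress (0.0650) lists did not pass. In the 6 alternatives with the same list test that kept all or all but 2 libraries, interneuron and meningeal lists passed in 4 each and choroid plexus markers in 3.

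Whether stigmasterol acted differently at the 2 times was tested directly. No gene passed. Podn, Vwf and Col3a1 were among the 10 genes with the smallest p, all of them with a negative difference between 6 h and 1 h. Lists of border tissues and vessels were called lower and GABA signalling and granule cell lists higher. None passed when the correlation was estimated (adjusted p = 0.619 or more), and 5 of the 8 were lost when single libraries were left out.

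With edgeR, 0 genes passed for this difference and 425 had an unadjusted p below 0.05 (118 positive, 307 negative); limma-voom, limma-trend and DESeq2 also gave 0. The matrix protein gene Podn had a difference of -1.03 ± 0.20 on the log2 scale, Vwf, the von Willebrand factor, -0.55 ± 0.12, Col3a1 -1.12 ± 0.31, Coch -1.21 ± 0.33, Tcirg1 -0.45 ± 0.13, Bmp4 -0.88 ± 0.25, Abi3bp -1.26 ± 0.37, Rbp4 -0.84 ± 0.24, Col1a1 -0.99 ± 0.29 and Dazap1 -0.34 ± 0.10, each with an adjusted p = 1.00. Of the 8 lists called, GABA signalling genes (Gad2 0.22 ± 0.11, Gad1 0.21 ± 0.11) and meningeal fibroblast markers passed in all 18 alternatives that used the same list test. With an estimated correlation the 8 lists had an adjusted p from 0.619 to 0.951.

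Most of these list differences lost their call without single libraries, given here as treatment, time and replicate with the adjusted p. A lost call does not by itself show that the median fell. Dentate granule cell markers did not pass without stigmasterol 1 h 11 (0.0880) or 8 (0.0538), stigmasterol 6 h 22 (0.199), vehicle 1 h 5 (0.0953). Their median was 0.22 with all libraries and between 0.14 and 0.20 in these repeats. Endothelial markers did not pass without stigmasterol 1 h 11 (0.0880) or 8 (0.107), stigmasterol 6 h 22 (0.285) or 23 (0.0972), vehicle 1 h 5 (0.238), vehicle 6 h 12 (0.160) or 21 (0.0995). Pericyte and smooth muscle markers did not pass without stigmasterol 1 h 1 (0.108) or 8 (0.0513), stigmasterol 6 h 22 (0.0967) or 23 (0.287), vehicle 1 h 5 (0.0953) or 9 (0.0588), vehicle 6 h 12 (0.0949) or 21 (0.0995). Ependymal markers did not pass without stigmasterol 1 h 11 (0.230) or 8 (0.0802), stigmasterol 6 h 13 (0.109) or 23 (0.452), vehicle 1 h 4 (0.104) or 9 (0.0527), vehicle 6 h 21 (0.428). Striatum markers did not pass without stigmasterol 1 h 8 (0.749), stigmasterol 6 h 22 (0.0967) or 23 (0.0972), vehicle 1 h 5 (0.0624), vehicle 6 h 21 (0.0901). Their median, -0.84 with all libraries, was 0.0950 without the first of these and between -0.94 and -0.73 without the others. Of the 6 alternatives with the same list test that kept all or all but 2 libraries, endothelial markers passed in 5, choroid plexus, striatum and ependymal markers in 3 each, and pericyte markers in 1.

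Between 1 h and 6 h after a vehicle injection, more genes passed the test than between stigmasterol and vehicle at either time. Bcl3, Ch25h, Lrg1, Vwf, Pdgfrb and the clock gene Per3 rose, and Homer1, Nfil3 and the calmodulin gene Calm2 fell. Inflammatory and pericyte lists were called higher and heat shock and endoplasmic reticulum stress lists lower. None of these lists passed when the correlation was estimated (adjusted p = 0.534 or more), and the endothelial list was not called.

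In vehicle mice, edgeR called 124 genes between 1 h and 6 h, 85 higher and 39 lower at 6 h. An unadjusted p below 0.05 was reached by 3901 genes (1940 higher, 1961 lower). DESeq2 called 1154 genes (544 higher, 610 lower), limma-voom 87 and limma-trend 154. The number was 3, 0 and 2 without vehicle replicate 4, 5 or 9 at 1 h, 1, 2 and 4 without replicate 12, 14 or 21 at 6 h, and 0 with choroid plexus content as a covariate. All 124 genes had groups that did not overlap, as did 33.3% of all genes where 10% would be met by chance.

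Bcl3 (chr7, 19808462 to 19822770), an NF-kappa-B cofactor, rose from 0.202 ± 0.0928 to 1.5 ± 0.273 CPM (SD, n = 3), a log2 fold change of 2.86 ± 0.30 (adjusted p = 0.00458). Its mean lay below the 1 CPM that the rule for naming genes required. Per3 fell outside that rule too, though not for its level. Both were chosen after their values were seen. Per3, a clock gene, rose from 70.5 ± 7.59 to 111 ± 4.48 CPM (SD, n = 3), with a log2 fold change of 0.66 ± 0.11 (adjusted p = 0.0303). Lrg1 (chr17, 56119678 to 56122001), an acute-phase glycoprotein of vessels, rose by 1.95 ± 0.28 on the log2 scale (adjusted p = 0.0256), and Ch25h, which makes 25-hydroxycholesterol, by 2.5 ± 0.35 (adjusted p = 0.0256). Ch25h was also at a low level, 0.156 to 0.396 CPM at 1 h and 1.39 to 1.81 CPM at 6 h. Vwf (chr6, 125546774 to 125686679) rose from 32.4 ± 1.73 to 55.8 ± 4.74 CPM (SD, n = 3), with a log2 fold change of 0.78 ± 0.09 (adjusted p = 0.00672). Grrp1 (1.65 ± 0.29), the hedgehog effector gene Gli1 (1.42 ± 0.21), Ifitm1 (1.28 ± 0.24), the collagen receptor gene Mrc2 (0.96 ± 0.20), Aox1 (0.95 ± 0.17), Plekho2 (0.93 ± 0.18), Podn (0.91 ± 0.14), Myh6 (0.86 ± 0.18), Sspo (0.85 ± 0.17) and Adcy4 (0.83 ± 0.13) rose at adjusted p from 0.0256 to 0.0478.

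Among the genes that fell, Homer1 (chr13, 93299635 to 93405129), a postsynaptic scaffold with an activity-induced short form, went from 99.7 ± 3.32 to 65.1 ± 4.23 CPM (SD, n = 3), a log2 fold change of -0.62 ± 0.11 (adjusted p = 0.0312). Calm2 went from 804 ± 16.8 to 546 ± 41.2 CPM (SD, n = 3), with -0.56 ± 0.10 (adjusted p = 0.0394). Nfil3 (chr13, 52967209 to 52981073), a repressor of clock output genes, had -0.65 ± 0.13 (adjusted p = 0.0432), Sap30 -0.70 ± 0.14 and the nucleolar protein gene Nifk -0.62 ± 0.09. Fam19a1 (-0.64 ± 0.12), Lurap1l (-0.62 ± 0.11), Galnt13 (-0.53 ± 0.10), the chemokine scavenger gene Ackr3 (-0.51 ± 0.10), Errfi1 (-0.51 ± 0.10), Tmem70 (-0.50 ± 0.10) and Fam118b (-0.50 ± 0.11) fell at adjusted p from 0.0324 to 0.0497.

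Inflammatory genes were higher at 6 h in vehicle mice in 19 of 23 cases (median log2 fold change 0.43, camera adjusted p = 0.000154, and adjusted p = 0.534 with an estimated correlation), with 2 genes past the threshold over all genes and 8 when adjusted over the list alone. The rotation test fry also called this list, pericyte and smooth muscle markers (both adjusted p = 0.0242, the latter with a camera adjusted p = 0.0650 without vehicle replicate 21 at 6 h) and heat shock genes (adjusted p = 0.0369). In the pericyte list (median 0.20, camera adjusted p = 0.0181, and adjusted p = 0.534 with an estimated correlation), Pdgfrb rose from 30.8 ± 3.34 to 46.0 ± 1.21 CPM (SD, n = 3) and Cspg4 rose by 0.49 ± 0.10 on the log2 scale (adjusted p = 0.0281 and 0.0432). Heat shock genes had a median of -0.25 (camera adjusted p = 0.000340, and adjusted p = 0.534 with an estimated correlation), 7 of 17 lower when adjusted over the list alone and none over all genes, led by Hsph1 (-0.37 ± 0.08) and Hsp90aa1 (-0.38 ± 0.09).

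Endoplasmic reticulum stress genes (median -0.19, camera adjusted p = 0.00151, led by Asns and Pdia6), GABA signalling genes (-0.13, 0.0135, Gabra4), CA3 pyramidal cell markers (-0.36, 0.0137, Cpne4 and Iyd), ribosomal protein genes (-0.11, 0.0356, Rpl23) and immediate early genes (-0.05, 0.0467, Homer1 and Nfil3) were called lower. Choroid plexus markers (1.23, 0.000154) and meningeal fibroblast markers (0.81, 0.00100, Col1a1 and Col1a2) were called higher. The choroid plexus median was 4.22 without vehicle replicate 5 at 1 h, -0.20 without vehicle replicates 4 and 9 at 1 h together and -0.0906 with plexus content as a covariate. With an estimated correlation these 7 lists had an adjusted p from 0.580 to 0.794. CA3 markers did not pass without vehicle replicate 5 at 1 h (adjusted p = 0.0660). Immediate early genes did not pass without that library (0.0567, with a median of -0.12) or vehicle replicate 21 at 6 h (0.172, with a median of -0.06). Ribosomal protein genes did not pass without vehicle replicate 4 at 1 h (0.345) or 21 at 6 h (0.429). Of the 6 alternatives with the same list test that kept all or all but 2 libraries, pericyte markers passed in 5, immediate early genes in 4, choroid plexus markers in 3 and ribosomal protein genes in 2.

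**Figure D4:**
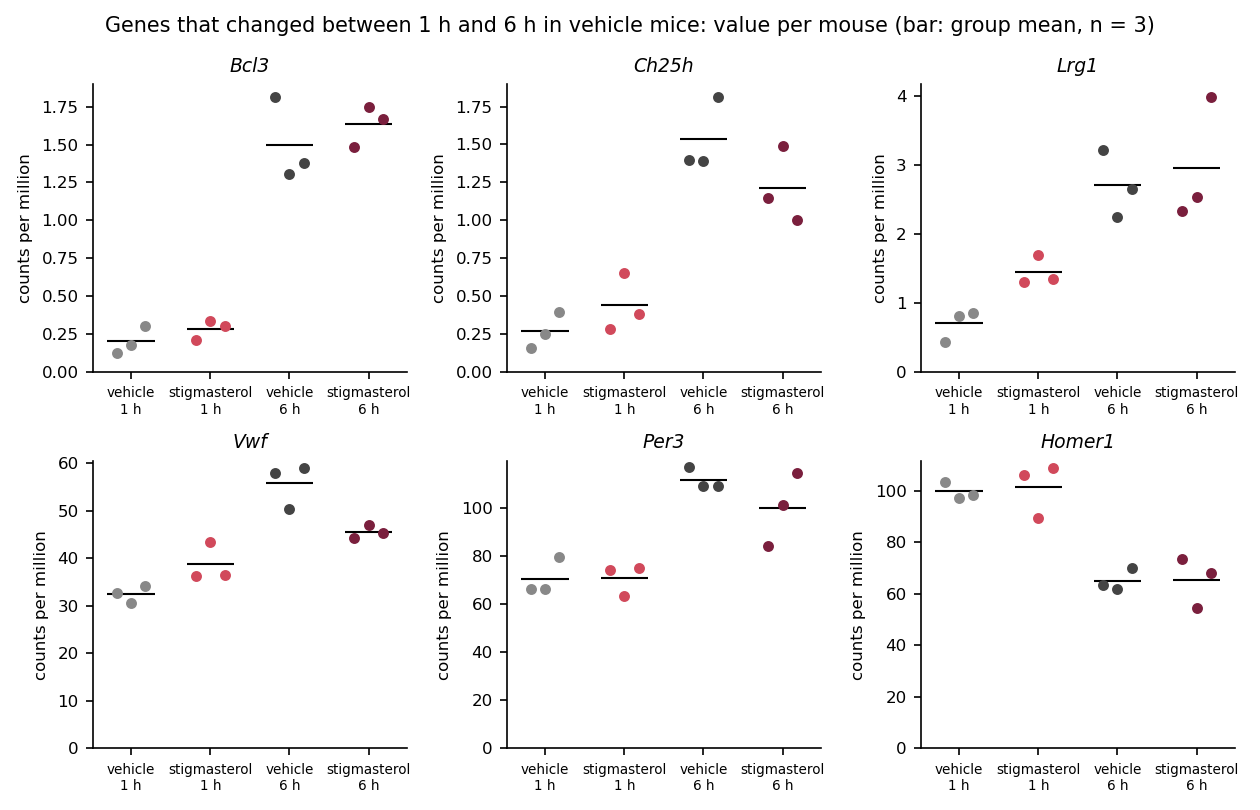
CPM of Bcl3, Ch25h, Lrg1, Vwf, Per3 and Homer1 in each mouse. Bars give the mean of 3 mice. Each gene passed an adjusted p of 0.05 between 1 h and 6 h in vehicle mice, and Bcl3 did so in stigmasterol mice.

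The same time interval in stigmasterol mice showed many shifts of the same sign. Bcl3 rose, and it was the single gene past the threshold. Stress-response and immediate early genes were lower at 6 h as lists, and inflammatory and astrocyte genes were higher. None of these lists passed when the correlation was estimated (adjusted p = 0.440 or more).

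With edgeR, 1 gene passed in stigmasterol mice, Bcl3, from 0.285 ± 0.0644 to 1.64 ± 0.136 CPM (SD, n = 3) and a log2 fold change of 2.51 ± 0.27 (adjusted p = 0.00575); 1837 genes had an unadjusted p below 0.05 (994 higher, 843 lower). DESeq2 called 97 genes (75 higher, 22 lower), and limma-voom and limma-trend 1 each. edgeR gave 0 genes without stigmasterol replicate 1 at 1 h, 2 without any other single library except replicate 23 at 6 h, and 5 without that one. Just above the threshold, with adjusted p from 0.0697 to 0.0941, were Phka1 (0.45 ± 0.06), Jak3 (0.73 ± 0.11), the Notch target Heyl (0.85 ± 0.13), Kcna4 (0.66 ± 0.10), Zfp46 (0.51 ± 0.08), Podxl (0.73 ± 0.12), Sox9 (0.56 ± 0.09), Homer1 (-0.63 ± 0.11), Kirrel2 (1.1 ± 0.20) and Dnajb1 (-0.48 ± 0.08). Groups did not overlap for 13.5% of genes, where 10% would be met by chance.

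Of the 124 genes called in vehicle mice, 122 (98.4%) had the same sign in stigmasterol mice and 100 also had an unadjusted p below 0.05 there. With each library's trend with GC content and length removed, 121 had the same sign and 80 an unadjusted p below 0.05. Their median signed log2 fold change in stigmasterol mice was then 0.225. Fold changes with time rose with GC content in both treatments (Spearman correlation 0.301 in vehicle and 0.177 in stigmasterol mice). Random lists of other genes had the same sign in 76.6% of genes at the median and in 83.9% at the 97.5th percentile. Those lists were matched on expression but not on size of change or GC content. The median signed log2 fold change of the 124 genes was 0.52 in vehicle mice, where they were selected, and 0.30 in stigmasterol mice. The 2 comparisons share no library, and the log2 fold changes of all genes correlated with Pearson r = 0.389.

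In stigmasterol mice all 17 heat shock genes were lower at 6 h (median -0.23, camera adjusted p = 1.03e-06), as were 19 of 20 endoplasmic reticulum stress genes (-0.24, 1.03e-06), of which 10 passed when adjusted over the list alone, led by Pdia4 (-0.54 ± 0.13) and Hspa5 (-0.51 ± 0.14). Immediate early genes were lower in 28 of 39 cases (-0.17, 8.38e-05), 10 of them when adjusted over the list alone, with Fosb at 5.53 ± 0.882 CPM against 11.2 ± 2.43 CPM (SD, n = 3). Inflammatory genes (0.41, 9.38e-05) were led by Ch25h (1.47 ± 0.32) and Lcn2 (3.67 ± 0.89, and 1.22 without stigmasterol replicate 23 at 6 h), and 7 were higher when adjusted over the list alone. Astrocyte markers had a median of 0.18 (9.38e-05), with Sox9 and Fgfr3 (0.49 ± 0.09) among 4 that were higher when adjusted over the list alone. No gene of these 5 lists passed over all genes, and with an estimated correlation the lists had an adjusted p from 0.440 to 0.517.

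CA3 pyramidal cell markers (median -0.26, camera adjusted p = 0.00370, Iyd and Cpne4), ribosomal protein genes (-0.09, 0.00951, Rpl23 and Rps16), striatum markers (-0.77, 0.0256, Tac1 and Adora2a) and choroid plexus markers (-0.65, 0.0272, Prlr and Sostdc1) were called lower and oligodendrocyte precursor markers (0.12, 0.0264, Cspg4 and Pdgfra) higher. With an estimated correlation their adjusted p lay between 0.517 and 0.969. Without stigmasterol replicate 8 at 1 h the striatum median was 0.01 (adjusted p = 0.653), and without replicate 23 at 6 h the list did not pass (0.215). Choroid plexus markers did not pass without replicate 8 (0.0716) or 11 (0.215) at 1 h or 13 (0.132) or 23 (0.570) at 6 h. Their median was -0.69, -0.32, -0.40 and -0.25 in that order. Ribosomal protein genes did not pass without replicate 8 at 1 h (0.0766) or 13 (0.192) or 23 (0.229) at 6 h. Oligodendrocyte precursor markers did not pass without replicate 1 (0.153) or 11 (0.0760) at 1 h or 13 at 6 h (0.239). Of the 5 alternatives with the same list test that kept all libraries, ribosomal protein and choroid plexus lists passed in 3 each and oligodendrocyte precursor markers in 2.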

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

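The predictions tested in this part were written after the result was seen. The plexus covariate, leaving out single libraries, the estimated correlation and fry were fixed with the design. For the difference of the stigmasterol effect between 6 h and 1 h, camera with a preset correlation called 8 gene lists. None passed with an estimated correlation (adjusted p = 0.619 or more) or with fry (0.696 or more). The median difference on the log2 scale was 0.14 for GABA signalling genes, 0.22 for dentate granule cell markers, -0.13 for endothelial markers, -0.14 for pericyte and smooth muscle markers, -1.88 for choroid plexus markers, -0.27 for ependymal markers, -1.01 for meningeal fibroblast markers and -0.84 for striatum markers. Camera adjusted p with a preset correlation was 0.000575, 0.00911, 0.0498, 0.0304, 1.27e-12, 0.0296, 5.65e-07 and 0.0266 in that order. The choroid plexus difference lay between -4.85, without vehicle replicate 5 at 1 h, and 0.0740, with plexus content as a covariate (adjusted p = 0.452), and the meningeal difference was -0.52 without stigmasterol replicate 11 at 1 h. Without stigmasterol replicate 8 at 1 h the striatum difference was 0.10 (adjusted p = 0.749). The endothelial difference was -0.0498 without stigmasterol replicate 22 at 6 h, and the pericyte difference -0.0556 without stigmasterol replicate 23 at 6 h. Without vehicle replicate 21 at 6 h the ependymal difference was -0.0765. The GABA signalling difference lay between 0.07 and 0.24 over the alternatives with the same list test. Of 50 splits, 38 gave at least 8 lists, the real split included in both numbers. The highest other gave 15, so chance cannot be excluded.

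Choroid plexus markers were higher after stigmasterol at 1 h and not at 6 h. Vehicle replicates 4 and 9 at 1 h were the 2 lowest libraries for 15 of 15 markers, while vehicle replicate 5 had a marker mean of 5.26, inside the 4.65 to 5.84 of the stigmasterol libraries. Replicates 4 and 9 had been noticed for the low mean of these same markers, so the count shows only that the markers fell together. Plexus tissue left on some hippocampi at dissection may explain the higher markers after stigmasterol at 1 h. It was not tested apart from these markers. The prediction for an effect of stigmasterol on plexus genes was that its 3 libraries lie above the vehicle libraries. It was not met, because of vehicle replicate 5. The exact permutation test of the marker mean gave p = 0.3 for a difference of 2.84. Such an effect is still not excluded, since 3 mice per group cannot give less than 0.1.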

How the results depend on the processing

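The alternatives with the trend with GC content and length removed, alone or with the plexus covariate, and with vehicle libraries 4 and 9 at 1 h both left out were chosen after seeing the data; the others were planned. No paired analysis was possible because replicate numbers are not shared between groups. Groups left with 1 library in a repeat were assumed to vary like the others. Among results past the threshold 255 repeats of named genes kept their side, 256 lost it and 0 reversed. The cause was not tested for the values below, except that a covariate built from plexus markers removes their difference by construction. DESeq2 gave 21 genes at 1 h, 4 at 6 h, 103 averaged, 1154 for time in vehicle and 97 in stigmasterol mice. At an adjusted p of 0.1 the counts were 7 averaged, 963 and 16. Time in vehicle mice gave 187 genes and in stigmasterol mice 8 with upper-quartile factors, 276 and 0 with the stricter filter, 1771 and 0 with only the groups compared, 512 and 13 with the GC and length trend removed, and 38 and 6 with the plexus covariate as well. It gave 0 in vehicle mice with the plexus covariate or with libraries 4 and 9 left out. The averaged effect gave 3 genes with no filter and 3 with the robust model. With an estimated correlation 0 lists passed in all 6 comparisons, and with fry 0 in 5 and 3 for time in vehicle mice. With plexus covariate and trend removal 16 lists passed for time in vehicle mice.

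With the plexus covariate the choroid plexus median was -0.0233 at 1 h, 0.00510 averaged, 0.0740 for the difference, -0.0906 for time in vehicle and 0.0544 in stigmasterol mice, the ependymal difference 0.13, and Sostdc1 -0.00830 at 1 h, 0.0740 for the difference and -0.27 for time in vehicle mice. With trend removal as well the choroid plexus median was -0.0145 at 1 h, 0.0646 for the difference, and -0.0342 and 0.0621 for time in vehicle and stigmasterol mice. The ependymal difference was then 0.11, Sostdc1 0.0646 for the difference and -0.14 for time in vehicle mice, ribosomal protein genes 0.0117 for time in vehicle mice, and Fos -0.0330 at 6 h. Without libraries 4 and 9 the choroid plexus median was 0.0152 at 1 h, -0.17 averaged and -0.20 for time in vehicle mice, Sostdc1 -0.0837 for time in vehicle mice and Fkbp5 -0.13 at 1 h. Fkbp5 at 1 h was -0.00489 with the trend removed, -0.00187 with the stricter filter and -0.00301 with upper-quartile factors.

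Leaving out 1 library, the lowest and highest values were 0 and 26 genes averaged, 0 and 4 for time in vehicle and 0 and 5 in stigmasterol mice; 9 and 16 lists at 1 h, 5 and 11 at 6 h and 4 and 10 for the difference; -0.12 and 0.31 for the correlation; -1.20 and 0.0950 for the striatum difference and -0.95 and 0.00886 for striatum with time in stigmasterol mice. For genes at 1 h they were -0.12 and 0.11 for Fkbp5 and -0.0433 and 0.0755 for Abca1. At 6 h they were -0.36 and 0.17 for Npas4, -0.0672 and 0.13 for Kpna1, -0.15 and 0.57 for Fos, -0.20 and 0.18 for Sgk1, -0.59 and 2.37 for Lcn2, and -0.0789 and 0.53 for Fkbp5.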

Other observations

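The predictions tested in this part were written after the results were seen, and removal of the GC and length trend was chosen then too. The plexus covariate was fixed with the design, and other splits were required of every comparison. The list of circadian clock genes was not called between 1 h and 6 h in either treatment. Among its members, log2 fold changes in vehicle and stigmasterol mice were 0.66 and 0.50 for Per3, 0.63 and 0.38 for Dbp, 0.47 and 0.33 for Cry1, 0.44 and 0.36 for Ciart, 0.41 and 0.31 for Usp2, 0.32 and -0.02 for Per2, -0.26 and -0.14 for Arntl, and -0.65 and -0.40 for Nfil3. Of these, Per3 and Nfil3 passed in vehicle mice and none in stigmasterol mice. The clock genes shown were chosen after their values were seen.

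The astrocyte genes Sox9 and Fgfr3 rose with time in vehicle mice, by 0.57 ± 0.09 and 0.55 ± 0.09 on the log2 scale (adjusted p = 0.0281 and 0.0269). The astrocyte list as a whole was not called there. Vehicle replicate 5 at 1 h held the most haemoglobin RNA, with Hbb-bs at 141 CPM against 46.8 CPM in the next library and Hba-a1 at 50.6 against 21.1 CPM.

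The 10 genes with the smallest p at 1 h were higher after stigmasterol, with a median log2 fold change of 0.79. Deeper libraries in the stigmasterol group at 1 h cannot account for the difference at 6 h, where totals were alike. There all 10 genes were higher, with a median of 0.552. The SE of the single genes had a median of 0.148, which is not an SE of that median. Whether depth added to the larger median at 1 h is not decided by these values. A trend of each library with GC content and length stays open as a part of the difference. With the trend removed the median was 0.430 (median single-gene SE 0.111) at 6 h, in libraries not used to choose the genes. Within groups, however, the mean of the genes still followed the GC slope of the library (correlation 0.514, and 0.814 before removal). Across the times, stigmasterol replicates 1 and 11 at 1 h and 23 at 6 h had GC slopes from -0.154 to -0.0660. Their 10-gene means were 3.83 to 4.09 log2 CPM. The vehicle libraries at 6 h had higher slopes, -0.0433 to 0.0802, and lower means, 3.48 to 3.53. This order argues against the GC slope as the only cause, though the 1 h libraries were used to choose the genes. An effect of stigmasterol stays open too. Of the 10 splits of the 6 h libraries the real split had the largest mean difference, 0.649 against 0.406 for the highest other. However, 10 splits are too few for a share under 0.05.

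The 124 genes that changed with time in vehicle mice had a median signed log2 fold change of 0.515 with the plexus covariate, against 0.52 without it. The median of the single-gene SEs was 0.118 and 0.0949 in that order. None of the 124 calls remained with the covariate, as the SE rose. With the trend with GC content and length removed the median was 0.419 (median single-gene SE 0.0857) and 96 calls remained. Within groups the genes then followed the GC slope with the opposite sign (correlation -0.667, and 0.578 before removal). Neither median can decide, because the genes were chosen for large changes in these same vehicle libraries. In stigmasterol mice, not used to choose them, the median signed log2 fold change was 0.299 with the plexus covariate. It was 0.225 there with the trend removed, so a shift in the same direction remained. Plexus content and the GC trend are not excluded as causes. Meningeal fibroblast markers were not used as a covariate. In vehicle mice their library means lay between 2.42 and 2.61 log2 CPM at 1 h and between 2.73 and 3.46 at 6 h. In stigmasterol mice the times overlapped, with 2.46 to 3.93 at 1 h and 2.75 to 3.21 at 6 h. A different clock time of tissue collection stays open. A score of clock genes differed between the times by 0.496 in an exact permutation test within treatment (p = 0.005 over 400 permutations), but its genes were chosen after the values were seen and the full clock list was not called. Clock time and time since injection cannot be told apart in this design. All 1 h mice had replicate numbers from 1 to 11 and all 6 h mice from 12 to 23. An order behind those numbers, which the labels do not explain, cannot be told apart from time either.

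For each comparison the libraries were also split in other ways. Each count of splits below includes the real split. At 1 h, 10 of 10 splits gave as many genes (real 0, highest other 0) and 1 of 10 as many lists (real 16, highest other 14). At 6 h, 10 of 10 gave as many genes (0 and 0) and 3 of 10 as many lists (9 and 12). For time in vehicle mice, 1 of 10 gave as many genes (124 and 0) and 4 of 10 as many lists (10 and 16). For time in stigmasterol mice, 2 of 10 gave as many genes (1 and 2002) and 7 of 10 as many lists (10 and 14). In these comparisons 10 splits are too few for a share under 0.05. The split with 2002 genes set stigmasterol replicates 1 and 11 at 1 h and 23 at 6 h against 8 at 1 h and 13 and 22 at 6 h, which points to a structure of the samples other than time. The GC slope, which is relative between libraries, was -0.154 to -0.0660 per 10 points on the first side and 0.102 to 0.290 on the other. Mitochondrial counts were 3.98 to 4.62% against 2.65 to 3.05%. For the averaged effect, 50 of 50 splits gave as many genes (0 and 0) and 3 of 50 as many lists (15 and 15). For the difference of effects 50 of 50 gave as many genes (0 and 0). The correlation between fold changes at 1 h and 6 h was as large in 6 of 50 (0.192 and 0.456). A real count of 0 genes is matched by every split by construction, so those gene counts say nothing about chance. Chance cannot be excluded for the other results.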
